A study of Mus musculus with 2 samples.

How the data were processed

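The data are 2 libraries of RNA from a nuclear or nucleoplasmic preparation (the label fields differ) of mouse bone marrow-derived macrophages. Per the labels, 1 µg of RNA went into replicate 1 and 500 ng into replicate 2. The labels call them biological replicates and give both the same donor identifier. Nothing says that they came from separate animals, so the spread between them may be partly technical, and SDs over 2 libraries are imprecise.

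For each library the authors deposited gene and transcript tables in the format of RSEM and a transcript table in the format of kallisto, called the second quantifier here. Per the readme files deposited with them, the genome is mm10 and the annotation GENCODE M21. The first pair was made from alignments to the transcriptome and the last from reads. The aligner, tool versions and the use of strand are not given in the sources used here. Per the file headers, the gene tables hold expected counts, TPM, a posterior mean TPM and bounds of a TPM interval whose level is not stated. The deposited expected counts are estimates that divide reads among transcripts and need not be whole. The deposited TPM divides each estimate by an effective length before scaling to a fixed total, so RNAs barely longer than a fragment receive large and unstable values. Genes with near-identical copies, overlapping genes and antisense genes can exchange counts. Signal tracks were not used here.

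All 55536 gene rows matched the M21 annotation, from which symbols, biotypes and coordinates come, and 86 of them have no row in the second quantifier. Gene IDs that share a symbol (Rmrp and Aldoa, 2 each) were summed within lists. Rows for phiX, spike-in controls and numeric identifiers were left out of the gene analyses; they held 1.19% of expected counts in replicate 1 and 0.215% in replicate 2. Expected counts totalled 23914018 in replicate 1 and 15721469 in replicate 2, and counts of the second quantifier 32262178 and 27066870. Intervals on shares of counts are 95% Wilson intervals, and a count of 0 allows 3 counts. Both cover counting error only, since the reads carry no molecular identifiers. The replicates differ beyond counting error, so they are not the same library deposited again. The 7SK RNA, for example, held 3.22% of expected counts in replicate 1 (95% Wilson interval 3.21 to 3.22). In replicate 2 it held 5.49% (5.48 to 5.50).

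The 24 gene lists were fixed with the tests before the data were examined. They cover immediate early genes, NF-kB subunits and inhibitors of their pathway (1 list), cytokines, chemokines, interferon-stimulated genes, antimicrobial effectors, the TLR4 pathway, macrophage identity, 6 other cell classes, nuclear RNAs, mitochondrial and ribosomal protein genes, histones, cell cycle, glycolysis, cholesterol synthesis, cholesterol efflux with LXR-related lipid genes, and chromatin regulators.

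With 1 group no contrast between conditions exists. A total of 4 pairs of lists were compared by the difference in mean log2(TPM + 0.1), averaged over both libraries, with a two-sided permutation test across genes (100000 resamples) and Benjamini-Hochberg adjustment over the 4. A list's level is described by the percentile of its median among 10000 random protein-coding lists of its size. Its ratio between replicates, over members of 1 TPM or more, is described by the percentile among 10000 lists matched in 20 bins of expression. Expected counts were rounded and normalised by TMM in edgeR 4.0.16 (R 4.3.3), which also gave the common dispersion of an intercept-only fit over 14052 genes with a mean of 10 or more counts. DESeq2 1.42.0 gave alternative size factors. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

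The genes named were set by rule: in each list described, the 4 highest members and up to 3 below 0.1 TPM in both libraries; the 15 highest genes; the 5 genes farthest apart between replicates in each direction among those of 10 TPM or more with separate deposited intervals; and 15 genes chosen beforehand, such as Tnf and Tlr4. Nuclear protein-coding genes were ranked separately after the values were seen, and Isg15 and Cmpk2 were also picked then. Some genes that the rule names are not reported here.

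Alternatives included other pseudocounts (1 and 0.01 TPM), the second quantifier, counts without length correction, the posterior mean, other floors and scalings, and each library alone. The steps were tested on simulated data. For 2 libraries at the real depths with 14055 genes, a true coefficient of variation of 22.4% was estimated as 25.3%, and with 14067 genes a true 10% as 16.4%, so the estimate runs high. At the former, 98% of 200 genes changed 4-fold were recovered as over 2-fold apart, with 6.08% of unchanged genes. The permutation test for the NF-kB and cytokine lists (41 genes) called 3.5% of 200 simulations with no shift, 37.5% with a shift of 1 on the log2 scale and 100% with a shift of 3. The simulated lists were drawn only from protein-coding genes with a mean of 1 TPM or more. Some real cytokine genes lay lower (lowest mean 0.22 TPM), so these rates may not hold for the real lists. The observed difference was not among the simulated shifts.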

Results

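Total RNA depleted of ribosomal RNA was sequenced from a nuclear preparation of mouse bone marrow-derived macrophages, primary cells of the strain C57BL/6J. The cells had been treated with 100 ng/ml Lipid A, the part of bacterial endotoxin that activates the receptor TLR4, for 12 hours. They were then kept without it for 12 hours and stimulated again at the same concentration for 60 min. The series holds 1 group of 2 biological replicates, so the comparisons are between gene groups within these libraries and between the replicates. Cells stimulated once, or not at all, were not analysed here, and no value below measures a response to Lipid A. Replicate 1 held 23630328 expected counts on annotated genes and replicate 2 held 15687634. The labels call the preparation nucleoplasmic in the description and nuclear in the source field, and which of these the levels refer to is open. Coordinates are on mm10, and levels are TPM, the length-corrected share of each transcript, as mean ± SD. TPM was not centred between the libraries, and the median nuclear protein-coding gene had a log2 ratio, replicate 2 over replicate 1, of -0.47. The SDs include this shift, so a small SD can mark a gene that rose relative to the others, such as Il1b (relative log2 ratio 0.55).

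Among nuclear protein-coding genes Psap, which encodes the precursor of the saposins (ENSMUSG00000004207.14, chromosome 10, 60277627 to 60302597), was highest at 4239 ± 1819 TPM (SD, n = 2). The class I histocompatibility gene H2-K1 had 3292 ± 979 TPM (SD, n = 2) and the cathepsin gene Ctsb 2052 ± 989 TPM (SD, n = 2). The ferritin heavy chain gene Fth1 had 1930 ± 949 TPM (SD, n = 2). These genes were chosen after the values were seen, because short RNAs fill most of the 15 highest places over all genes. The acute-phase gene Saa3 (1636 ± 1128 TPM; SD, n = 2), Tnf and Ccl5 also stood among the 20 highest. In both libraries 8786 of 22028 annotated protein-coding genes reached 1 TPM, 3281 reached 10 TPM and 315 reached 100 TPM. With a floor of 5 TPM the number was 5087.

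Genes induced through type I interferon stood above immediate early genes. All 28 interferon-stimulated genes reached 10 TPM in both libraries, and their median was 242 TPM in replicate 1 and 117 TPM in replicate 2. The antiviral gene Rsad2 had 1087 ± 657 TPM (SD, n = 2), Ifit2 723 ± 425 TPM (SD, n = 2), Oasl2 572 ± 85.2 TPM (SD, n = 2) and Mx1 468 ± 374 TPM (SD, n = 2). Of 20 immediate early genes, which respond to stimuli within minutes, 18 reached 1 TPM and 4 reached 100 TPM in both libraries. The transcription factor gene Klf6 had 275 ± 67.5 TPM (SD, n = 2) and Zfp36, which encodes a protein that destabilises cytokine messages, 259 ± 85.0 TPM (SD, n = 2). Junb had 157 ± 70.0 TPM (SD, n = 2) and the phosphatase gene Dusp1 133 ± 23.6 TPM (SD, n = 2). On the log2(TPM + 0.1) scale the immediate early mean minus the interferon-stimulated mean was -2.86 ± 0.51 (SD, n = 2), with p = 1e-05 in a two-sided permutation test across genes, the smallest that the resamples can give. The Benjamini-Hochberg adjusted p over the 4 list comparisons was 2e-05. Genes of a list are not independent replicates, so this p describes these lists in these libraries.

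Genes of the NF-kB list, which holds NF-kB subunits such as Rela and Nfkb1 as well as inhibitors of the pathway, were all present. All 21 reached 1 TPM in both libraries and 19 reached 10 TPM. Tnfaip3, the ubiquitin-editing enzyme A20 (ENSMUSG00000019850.11, chromosome 10, 19000910 to 19015657), had 462 ± 73.5 TPM (SD, n = 2). Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm, had 360 ± 158 TPM (SD, n = 2), Tnip3 317 ± 68.7 TPM (SD, n = 2) and Nfkbiz 278 ± 46.7 TPM (SD, n = 2). The cytokine signalling inhibitor Socs3 had 161 ± 39.3 TPM (SD, n = 2), and Irak3, a kinase-like inhibitor of Toll-like receptor signalling, 22.9 ± 4.29 TPM (SD, n = 2). Of 20 inflammatory cytokine genes, 15 reached 1 TPM in both libraries. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) had 1212 ± 301 TPM (SD, n = 2), Il1a 286 ± 48.8 TPM (SD, n = 2), Il1b 249 ± 9.38 TPM (SD, n = 2) and Tnfsf9 230 ± 7.45 TPM (SD, n = 2). Il6 had 16.3 ± 2.92 TPM (SD, n = 2), Il12b 17.5 ± 7.57 TPM (SD, n = 2), Il10 26.4 ± 2.10 TPM (SD, n = 2) and the interferon gene Ifnb1 20.3 ± 6.28 TPM (SD, n = 2). The mean of the NF-kB list minus the cytokine mean was 1.86 ± 0.32 on the log2 scale (SD, n = 2), with p = 0.0383 and an adjusted p = 0.0511 in the two-sided permutation test across genes, so the difference did not pass 0.05. In replicate 1 alone it was 2.08 with an adjusted permutation p = 0.0286, and it also passed with the second quantifier (1.76, adjusted permutation p = 0.0425) and with counts not corrected for length (2.83, adjusted permutation p = 0.00552). In replicate 2 alone it was 1.63 with an adjusted permutation p = 0.0913.

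Antimicrobial effector genes and cytokine genes were not separated by their mean level. Of 22 effector genes, 17 reached 1 TPM in both libraries. Acod1, the enzyme that makes itaconate (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573), had 1109 ± 262 TPM (SD, n = 2). The lectin receptor gene Clec4e had 807 ± 79.4 TPM (SD, n = 2) and the NADPH oxidase gene Cybb 410 ± 59.5 TPM (SD, n = 2). Nos2, the inducible nitric oxide synthase, had 4.97 ± 3.12 TPM (SD, n = 2), and the cathelicidin gene Camp was below 0.1 TPM in both libraries. The effector mean minus the cytokine mean was 0.28 ± 0.47 on the log2 scale (SD, n = 2), smaller than the spread between replicates, with p = 0.811 and an adjusted p = 0.811 in the two-sided permutation test across genes. In replicate 2 alone it was -0.060.

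**Figure D1:**
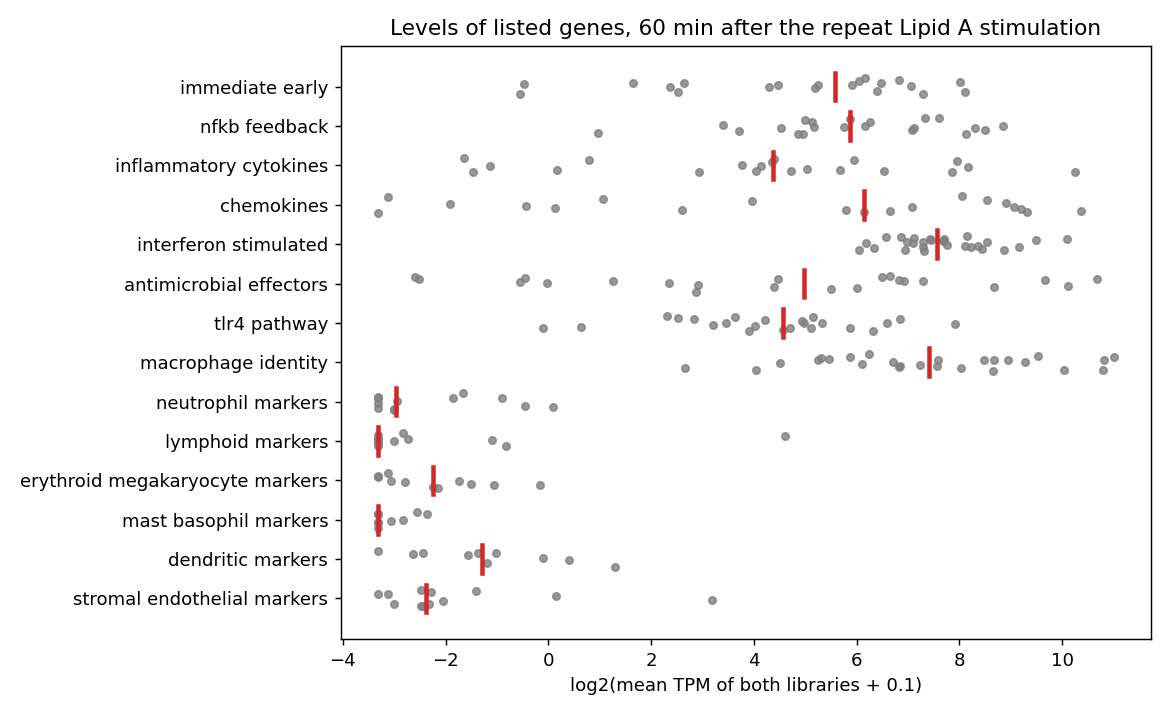
Each grey point is a gene, placed by log2 of its mean TPM over both libraries plus 0.1, in rows of gene lists fixed before the data were examined; the red bar is the list's median. Interferon-stimulated and macrophage genes sit to the right, and the 6 lists of other cell types sit near the left end, with Cd4 and Kdr as the points farthest from their lists.

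Chemokine genes ranged from absent to among the highest. Of 19, 14 reached 1 TPM and 8 reached 100 TPM in both libraries. Ccl5 had 1326 ± 615 TPM (SD, n = 2), Cxcl10 634 ± 367 TPM (SD, n = 2), Ccl4 588 ± 265 TPM (SD, n = 2) and Ccl3 536 ± 35.6 TPM (SD, n = 2). Ccl17 had 0 counts in both libraries, which allows up to 0.372 TPM in replicate 1 and 0.430 TPM in replicate 2, and Cxcl5 stayed below 0.1 TPM in both, against a mean of 0.699 TPM from the second quantifier. Of 23 genes of the TLR4 pathway, 22 reached 1 TPM in both libraries. The co-receptor gene Cd14 had 240 ± 25.3 TPM (SD, n = 2), Tlr2 114 ± 29.5 TPM (SD, n = 2), Irak2 96.5 ± 21.1 TPM (SD, n = 2) and Tbk1 79.9 ± 25.6 TPM (SD, n = 2). Each of the 8 lists of response, TLR4 pathway and macrophage genes had a median above all 10000 random protein-coding lists of its size. Those random lists were drawn from all annotated protein-coding genes, most of which did not reach 1 TPM in both libraries. The central 95% of their medians ran from 0 to at most 3.88 TPM. The percentile therefore mainly shows that these lists are expressed, and the ribosomal and glycolysis lists reached the same percentile. Tlr4 itself (ENSMUSG00000039005.13, chromosome 4, 66827584 to 66930284) had 18.4 ± 8.22 TPM (SD, n = 2).

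Macrophage genes were high and markers of other cells were near 0. All 26 macrophage genes reached 1 TPM in both libraries, led by Ctsb, Lyz2 (lysozyme, 1812 ± 564 TPM; SD, n = 2), Ctsd (1775 ± 696 TPM; SD, n = 2) and Sirpa (1051 ± 420 TPM; SD, n = 2). Among 12 neutrophil markers and 11 erythroid and megakaryocyte markers, 0 reached 1 TPM in both libraries, and the same held for 9 mast cell and basophil markers. The highest were Mmp8 (0.960 ± 0.028 TPM; SD, n = 2), Alas2 (0.790 ± 0.226 TPM; SD, n = 2) and Gata2 (0.095 ± 0.120 TPM; SD, n = 2). With TPM rescaled over nuclear protein-coding genes, chosen after seeing the data, 2 neutrophil, 1 erythroid, 3 lymphoid, 3 dendritic and 2 stromal markers reached 1 TPM. The neutrophil genes Ly6g, Mpo and Elane stayed below 0.1 TPM in both libraries, but the posterior means were 0.415 TPM for Mpo and 0.385 TPM for Ly6g. Of 13 lymphoid markers 1 reached 1 TPM, Cd4, at 24.2 ± 5.01 TPM (SD, n = 2). Cd3e had 0 counts in both libraries, which allows up to 0.111 TPM in replicate 1 and 0.125 TPM in replicate 2. Of 10 dendritic cell markers 1 reached 1 TPM, Batf3, at 2.37 ± 1.26 TPM (SD, n = 2), and of 12 stromal and endothelial markers 1, Kdr, at 8.94 ± 6.79 TPM (SD, n = 2). The medians of these 6 lists lay between percentiles 4.17 and 45.6 of random lists. The macrophage mean minus the mean of the 67 other markers was 9.49 ± 0.35 on the log2 scale (SD, n = 2), with p = 1e-05 and an adjusted p = 2e-05 in the two-sided permutation test across genes.

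Short RNAs had the highest TPM of all genes. The 7SK RNA, Rn7sk, which holds the elongation factor P-TEFb inactive (ENSMUSG00000065037.1, chromosome 9, 78175303 to 78175633), took 226393 TPM in replicate 1 and 314711 TPM in replicate 2. Rpph1, the RNA of RNase P, took 47770 and 118026 TPM. The 15 highest genes also held both IDs of Rmrp, the signal recognition particle RNAs Rn7s1 and Rn7s2 with identical values (46519.8 TPM each), the small nuclear RNA rows Gm22513, Gm25939, Gm23472 and Gm23444, and the Cajal body RNA Gm22009. The other places went to Malat1, mt-Atp8, mt-Co1 and Gm28661, a nuclear copy of mt-Co2. Malat1, a long RNA of nuclear speckles (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), had 19601 ± 946 TPM (SD, n = 2) and 9.35% of expected counts in replicate 1 (95% Wilson interval 9.34 to 9.37) and 9.62% in replicate 2 (9.61 to 9.63). Neat1, the scaffold of paraspeckles, had 705 ± 317 TPM (SD, n = 2), Xist 112 ± 13.4 TPM (SD, n = 2) and Dleu2 59.0 ± 12.6 TPM (SD, n = 2). Of 13 long nuclear RNAs 10 reached 1 TPM in both libraries, and of 10 small nuclear RNAs 6 did, against 9 with the second quantifier. Rnu73b and Rny1 have 0 counts in the gene tables, and the second quantifier gave them means of 30.4 and 4.50 TPM. Protein-coding genes held 28.6 ± 5.01% of TPM (SD, n = 2) but 77.2 ± 3.05% of expected counts (SD, n = 2). The biotype that holds 7SK and the signal recognition particle RNAs had 36.4 ± 4.25% of TPM (SD, n = 2), and 12.3% as the mean of both libraries from the second quantifier. It had 5.47 ± 1.51% of expected counts (SD, n = 2), and Rn7sk had 3.22% in replicate 1 and 5.49% in replicate 2, below Malat1.

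The 13 mitochondrial protein-coding genes held 5.14 ± 1.59% of TPM (SD, n = 2). The share was 4.01% in replicate 1 and 6.26% in replicate 2, and 18.7 ± 8.84% (SD, n = 2) of the TPM of protein-coding genes alone. By expected counts it was 3.37% and 5.91%. The TPM share leans on the short gene mt-Atp8, with effective lengths of 27.6 bases in replicate 1 and 20.3 in replicate 2. It had 8685 and 24305 TPM. The cytochrome oxidase gene mt-Co1 had 12790 ± 2099 TPM (SD, n = 2) and mt-Nd1 3268 ± 1366 TPM (SD, n = 2). Transcripts annotated as retained introns held 15.1 ± 0.296% of the TPM of protein-coding genes (SD, n = 2). That total includes the mitochondrial genes, whose part of it was larger in replicate 2. The small SD therefore does not show that the retained share of nuclear genes was unchanged. By expected counts the retained share was 11.1% in replicate 1 and 13.1% in replicate 2. From the second quantifier, which puts 35.6% of TPM on microRNA rows and 26.8% on processed pseudogenes, the mitochondrial share was 2.27 ± 1.32% (SD, n = 2).

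The replicates differed in their interferon-stimulated and cytokine genes. Relative to the median nuclear protein-coding gene, 23 of 27 interferon-stimulated genes (without Mx2, annotated as a polymorphic pseudogene) were lower in replicate 2, and the list's median log2 ratio was -0.52, below all 10000 random lists matched on expression (central 95% -0.32 to 0.03). Mx1 had 732 TPM in replicate 1 and 204 TPM in replicate 2, Cmpk2 436 and 119 TPM, and Isg15 326 and 92.9 TPM. Of 17 inflammatory cytokine genes 5 were relatively lower in replicate 2, and the median log2 ratio was 0.55, above all matched lists (central 95% -0.28 to 0.17). Il12b had 12.1 TPM in replicate 1 and 22.8 TPM in replicate 2. Tnf, the highest cytokine gene, had 1424 and 999 TPM and lay near the median gene (relative log2 ratio -0.04). These TPM pairs are not centred and include the log2 shift of -0.47 of the median gene. The medians of the effector genes (-0.37, percentile 0.525), macrophage genes (-0.36, percentile 0.350) replication histones (-0.28, percentile 1.47) and ribosomal protein genes (-0.25, percentile 0) also lay below the central 95%. These values compare 2 libraries and have no test. Genes of a list are not independent, while the random lists are drawn gene by gene, so an extreme percentile is not a p-value.

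**Figure D2:**
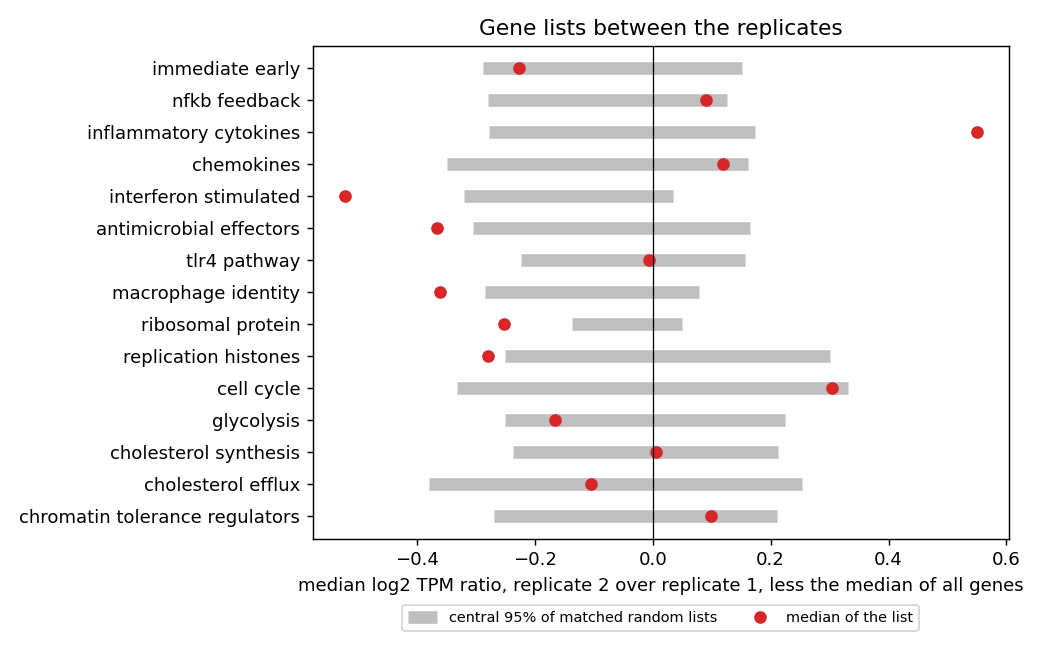
Red points are the median log2 TPM ratio of each gene list, replicate 2 over replicate 1, less the median of all nuclear protein-coding genes; grey bars span the central 95% of 10000 random lists matched on expression. The cytokine list lies at 0.55 and the interferon-stimulated list at -0.52, both outside their bars.

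Over all genes, 1207 of 14052 with a mean of 10 or more expected counts were over 2-fold apart between the replicates (8.59%), 623 higher in replicate 2 and 584 higher in replicate 1. With TPM in place of TMM-normalised counts the number was 1878, of which 181 were higher in replicate 2. The TPM of the median nuclear protein-coding gene differed by -0.47 on the log2 scale, replicate 2 over replicate 1. It differed by 0.096 with TPM rescaled over nuclear protein-coding genes and by 0.37 in the TPM of the second quantifier. There microRNA rows took 43.6% of TPM in replicate 1 and 27.6% in replicate 2. The direction of this shift therefore depends on the quantifier and the scaling. With the second quantifier 2637 of 22331 genes (11.8%) were over 2-fold apart, of which 1774 were higher in replicate 2. The common biological coefficient of variation in edgeR was 22.7%. Across all 22028 annotated protein-coding genes, which are not independent replicates, Pearson's r of log2(TPM + 0.1) was 0.989 and Spearman's rho 0.972. Only 8786 of these genes reached 1 TPM in both libraries, so genes at or near 0 enter both values. By the planned rule the genes farthest apart were small RNAs with effective lengths of 1.29 to 1.91 bases in replicate 1 and 0 in replicate 2, namely Snord22 (11251 TPM in replicate 1 and listed at 0 in replicate 2), Gm26447, Snora68, Snora78 and Gm25541. On the other side were Gm38317, Gbp10, Gm25291, Gm24727 and Plaur. Plaur, the urokinase receptor gene, had 7.36 TPM in replicate 1 and 23.1 TPM in replicate 2. Among named nuclear protein-coding genes, chosen after the values were seen, Galnt2, Ifit1bl1 and the complement gene Cfb (148 and 32.2 TPM) were farthest apart in the direction of replicate 1.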

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

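Some rows left out of the gene analyses, and some gene rows not described above, carried counts above the 3 that a count of 0 allows. The phiX sequencing control held 1.19% of expected counts in replicate 1 and 0.215% in replicate 2. Rows with numeric identifiers held 13.0 and 5 expected counts. The second quantifier put 269353 and 92989 counts on Gm24270, a microRNA row with 0 in the gene tables, and 791262 and 582968 counts on the pseudogene Gm12896. Of the tests below, only those of GC content and length were set before their results were seen.

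The first pattern is the interferon-stimulated genes being relatively lower, and the cytokine genes relatively higher, in replicate 2. Centring the ratios in bins of GC content and effective length left medians of -0.59 and 0.51, against -0.52 and 0.55 before, so such a bias does not account for it. The second quantifier gave -0.50 and 0.43, which argues against the quantifier. Less cytosolic RNA in replicate 2 would spare retained-intron isoforms. Those of 16 interferon-stimulated genes had a median of -0.58, taken relative to the retained-intron isoforms of all genes. This lay below the central 95% of random lists (-0.50 to 0.11). Their other isoforms had -0.27, taken relative to the other isoforms of all genes, so the 2 medians have separate baselines. Within genes the retained share rose in most, as in Ifih1 (53.2% to 65.4%), and fell in others, as in Mx1 (14.8% to 12.5%). Over 2291 protein-coding genes with such an isoform, the median retained share also rose, from 23.1% in replicate 1 to 25.6% in replicate 2. The test therefore does not decide how far cytosolic RNA matters. With 2 usable cytokine genes that part was not tested. No biological explanation was tested, and a difference between cultures, in the timing of the stimulation or in input RNA stays open.

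The second pattern is the larger part taken by 7SK, RNase P RNA and mitochondrial RNA in replicate 2. Other short RNAs did not all rise. Rn7s1 and Rn7s2 each held 0.593% of expected counts in replicate 1 and 0.522% in replicate 2, and the small nuclear RNA biotype 0.184% and 0.138%. Shares of counts hold no effective length, and the smaller of the ratios for Rn7sk and Rpph1, replicate 2 over replicate 1, was 1.71. The second quantifier gave 1.56. For the mitochondrial genes with their nuclear copies the ratios were 1.79 and 1.77, so neither effective lengths nor the quantifier account for the pattern. A difference in fractionation or in library preparation was not tested, nor was a biological explanation.

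The third pattern is mt-Co3, at 1086 TPM in replicate 1 and 372 in replicate 2 while mt-Nd1 had 2302 and 4234. The genes mt-Co2, mt-Atp6 and mt-Nd4l also had lower count shares in replicate 2 (ratios 0.896, 0.821 and 0.589). With the second quantifier only mt-Co2 of these stayed lower (0.794). There mt-Co3, mt-Atp6 and mt-Nd4l rose (ratios 1.16, 2.14 and 2.23). A candidate explanation is reads shared with the pseudogene Gm28437 (chromosome 1, 24613189 to 24613971), all of whose 31-base words occur in mitochondrial genes. Counted together, mt-Co3 and this copy had a ratio of count shares of 1.41, against 0.455 for mt-Co3 alone and 1.31 to 2.45 for the 5 mitochondrial genes without a copy, and the other 3 with their copies had 1.32, 1.99 and 1.97. No biological explanation was tested.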

How the results depend on the processing

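Of the list comparisons, immediate early minus interferon-stimulated and macrophage minus other markers kept their direction and passed 0.05 under every alternative run. Their sizes moved more. The former (-2.86) was -1.88 with the median of members and -3.22 to -2.50 with a replicate left out. The latter (9.49) was 7.02 with a pseudocount of 1 TPM, 11.24 with 0.01 TPM and 9.24 to 9.74 with a replicate left out. NF-kB minus cytokine genes (1.86, adjusted permutation p = 0.0511) did not pass with a pseudocount of 1 TPM (adjusted p = 0.0693) or with members at 0.1 TPM or more only (adjusted p = 0.0948). Nor did it pass with the posterior mean (adjusted p = 0.0544), the median of members (adjusted p = 0.0511) or replicate 2 alone (adjusted p = 0.0913). It passed 0.05 with a pseudocount of 0.01 TPM (2.00), the second quantifier (1.76), counts without length correction (2.83) and replicate 1 alone (2.08). Chosen after seeing the data, TPM rescaled over nuclear protein-coding genes also passed (1.96). The difference ranged from 1.63 to 2.08 with a replicate left out, and the adjusted p over all settings from 0.00552 to 0.0948. Effector minus cytokine genes ranged from -0.060 to 0.61 with a replicate left out, a change of sign in a difference that passed no test. The causes were not tested. Genes detected fell from 8786 to 5087 at 5 TPM. Genes over 2-fold apart (1207) numbered 4858 with no filter, 265 at 100 counts, 1878 with TPM, 2637 with the second quantifier, out of 22331 genes in place of 14052, and, chosen afterwards, 627 for nuclear protein-coding genes, fewer genes being tested. Of those apart, 51.6% were higher in replicate 2 with TMM, 9.64% with TPM and 67.3% with the second quantifier. The mitochondrial share (5.14%) was 2.27% with the second quantifier, 18.7% of protein-coding TPM and, chosen afterwards, 7.30% with nuclear copies. The retained intron share (15.1%) was 12.1% of expected counts and 18.0% with the second quantifier. Of 179 named-gene means, 39 moved by over 1 SD with the posterior mean. That count depends on the SD over 2 libraries. Acod1 fell from 1109 to 1062 TPM and Abca1 from 154 to 148 TPM, and only Abca1, with the smaller SD, counted as moved. With the second quantifier 121 means moved by over 1 SD. MicroRNA and processed pseudogene rows take 35.6% and 26.8% of its TPM and lower other genes together, so this number does not describe single genes. Rescaling TPM over nuclear protein-coding genes, chosen afterwards, moved replication histones at 1 TPM from 11 to 23 and cell cycle genes from 9 to 16; the second quantifier gave 6 histones. No paired analysis was possible because the series has 1 group. Depth limits markers near 0, where a few counts set the value.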

Other observations

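Some genes had most of their RNA on isoforms annotated as retained introns. Among 2291 protein-coding genes of 10 TPM or more with such an isoform, 238 (10.4%) had over 50% of their TPM on it in both libraries, and 193 of these also with the second quantifier. Of 158 such genes in the fixed lists, 14 (8.86%) had over 50% in both libraries from the gene tables' quantifier. The inhibitory receptor gene Lilrb4a had 96.9 ± 0.684% (SD, n = 2), the signalling gene Malt1 71.1 ± 0.179% (SD, n = 2), Tnip3 75.8 ± 1.18% (SD, n = 2), Clec4e 67.3 ± 4.91% (SD, n = 2) and the activation marker Cd83 82.0 ± 5.08% (SD, n = 2). Nfkb1 had 76.6 ± 2.43% (SD, n = 2) and Irf7 55.9 ± 5.45% (SD, n = 2). These genes were picked after their values were seen, and reads of unspliced RNA also count toward such isoforms.

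The medians of the ribosomal, glycolysis, efflux, chromatin and mitochondrial lists lay above all 10000 random lists, with cholesterol synthesis at percentile 99.7, replication histones at 79.4 and cell cycle at 76.6. Most genes behind the random lists did not reach 1 TPM, so a high percentile mainly shows that a list is expressed. All 80 ribosomal protein genes reached 1 TPM in both libraries, with a median of 32.8 ± 12.2 TPM (SD, n = 2), led by Rps24 at 148 ± 0.764 TPM (SD, n = 2). Glycolysis genes had a median of 21.5 ± 7.87 TPM (SD, n = 2), led by Pkm at 82.9 ± 17.5 TPM (SD, n = 2). All 9 genes of the cholesterol efflux list, which also holds the LXR receptor genes Nr1h2 and Nr1h3 and the desaturase gene Scd2, reached 1 TPM, with Abca1 at 154 ± 2.52 TPM (SD, n = 2), as did all 16 cholesterol synthesis genes, with Insig1 at 37.1 ± 10.8 TPM (SD, n = 2). All 15 chromatin regulators reached 1 TPM, with the corepressor gene Ncor1 at 64.0 ± 5.65 TPM (SD, n = 2). With the TPM of all genes, of 20 cell cycle genes 9 reached 1 TPM in both libraries, with Mki67 at 45.8 ± 3.82 TPM (SD, n = 2), and of 31 replication histone genes 11 did, with Hist1h2bc at 7.97 ± 2.67 TPM (SD, n = 2).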
